A study of Mus musculus with 6 samples.

How the data were processed

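Total RNA from 6 samples of AML12 cells, 3 labelled siCtrl and 3 labelled siUhrf2 after 72 h, was sequenced by Illumina RNA-seq, per the labels. Groups and replicate numbers were taken from the sample titles, and table columns were matched to samples by the same names, with 0 columns left unused. The sequences of both siRNAs and the position of the target site in Uhrf2 are not given in the sources used here.

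The authors deposited 1 table with a normalized count, a signal that is never negative, and an FPKM value per gene and library, per the file headers. The submitters' processing notes name kallisto 0.44.0, the build GRCm38.p6 and edgeR, without saying which step each tool served. How transcripts were summed to genes, the annotation release, the use of strand and any filter are not given in the sources used here. In each library the most frequent low value gave what 1 read was worth, between 0.922 and 1.09 normalized units, and dividing by it gave 44.6 to 53.1 M estimated reads per library. Between 63.0% and 64.9% of the values above 0 were whole reads within 0.01 read, so the deposited normalized signal was not treated as counts. The deposited FPKM values equalled the normalized count divided by 1 length per gene and by the library's total, as checked on all genes above 0 in every library. Relative precision is lower for genes with few reads, which short or weakly expressed genes have.

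Ensembl identifiers were matched to GENCODE M21 on GRCm38 and to the symbol table given with it: 35574 of 35709 had a symbol and 135 did not, and 10781 genes were at 0 in all libraries. Coordinates are 1-based. The symbol Aldoa stood for 2 identifiers, which count as 2 entries of its list. Within groups, replicate pairs had Pearson r of 0.995 to 0.997 across genes, which are not independent replicates. Estimated reads differed by more than sampling noise in every pair (chi-square per degree of freedom 3.14 to 12.2), so each library counted as 1 sample. In both groups the pairs with replicate 1 had the higher values, 7.71 to 12.2. Replicates 2 and 3 had 4.28 in siCtrl and 3.14 in siUhrf2.

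The design written before the data were examined foresaw a count test (edgeR) for counts, but the table held no column of whole counts and edgeR was not run here. The test fitting the unit was used in its place: limma 3.58.1 (R 4.3.3, statmod 1.5.0) with a mean-variance trend and robust variances on log2(normalized count + 1), for the 11343 genes with a mean of at least 1 FPKM over the 6 samples. The log2 values were computed from the deposited normalized counts. Fold changes are on this log2(value + 1) scale, which understates changes of low genes, and folds given as such are 2 to the power of that log2 change. A gene was called at a Benjamini-Hochberg adjusted p under 0.05. No batch is named in the labels, and no covariate was used. The exact permutation test of Uhrf2 and Uhrf1 was two-sided over all splits.

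A set of 24 gene lists with 626 distinct genes was fixed before the data were examined. They covered the UHRF family and DNA methylation, G1/S and DNA replication, G2/M and mitosis, p53 targets, unfolded protein response, cholesterol synthesis, fatty acid synthesis, fatty acid oxidation, hepatocyte secreted proteins and transcription factors, cytochrome P450 and conjugation, central carbon metabolism, interferon response, NF-kB and acute phase, extracellular matrix, NRF2, oxidative phosphorylation, ribosomal proteins, germline and imprinted genes, siRNA machinery, apoptosis, and 4 sets of markers of other cell types. Lists were tested with camera in limma at a preset inter-gene correlation of 0.01, again with the correlation estimated, and with fry, each adjusted over the lists. Members were also counted after adjustment over the list alone.

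Genes were named by a rule fixed before the data were examined: Uhrf2 and Uhrf1, the 12 largest rises and 12 largest falls among called genes with a mean of at least 5 FPKM whose groups did not overlap, without predicted genes lacking a proper symbol, and up to 4 members per list with the smallest adjusted p at that level. Members named in addition because a count was 5 or fewer, and Dnmt1, were chosen after their values were seen. Some genes that the rule takes are not reported here.

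The fit was tested on simulated data for this comparison, with 11343 genes of which 200 were changed by known folds. It recovered 33 of 50 genes changed 1.25-fold, 41 of 50 at 1.5-fold, 47 of 50 at 2-fold and 49 of 50 at 3-fold, with 9 false calls among 179 (5.03%). Camera was tested on separate simulated data, in which only 1 list of 30 genes was moved, by 1.2-fold, and genes were drawn independently. It called 1 of 1 moved list and 0 of 24 unmoved lists there. In the data it called 4 to 10 lists in each of the 9 splits that mixed the groups. Those splits keep part of the siUhrf2 difference, so they are not a counterpart of the unmoved lists.

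Alternatives covered 4 other scalings of the libraries, the pseudocount, the filter on low values, limma-voom on estimated reads, limma treat against 1.5-fold, a stricter threshold, a replicate block and leaving out each library. Tables were handled with Python 3.11.15, numpy 2.4.6, scipy 1.17.1 and pandas 2.3.3, and plots drawn with matplotlib 3.10.9. Base composition was tested 3 times after the scan was seen. A count of same-letter heptamers that scored as high (0 of 419) and the adjusted mean log2 fold change of genes with TCGGAGA (0.179) against the median over these heptamers (0.00287, SD 0.0197) did not allow for the pick of TCGGAGA by its rank, so the test reported set its distance above them against the largest such distance in each shuffle.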

Results

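RNA-seq profiles were compared between AML12 cells, a non-tumorigenic mouse hepatocyte line, treated for 72 h with a small interfering RNA against Uhrf2 (siUhrf2) or with a scrambled one (siCtrl). Uhrf2 encodes a RING-type ubiquitin ligase that binds modified DNA and is the paralog of the DNA methylation cofactor Uhrf1. Each group held 3 libraries of total RNA, and the comparison asked which transcripts differ after Uhrf2 knock-down. The table listed 35709 genes with normalized counts and FPKM values. Library depth, recovered from the most frequent low value, lay between 44.6 and 53.1 M estimated reads, and the 10 most abundant genes took between 7.34% and 8.31% of the total. Replicates were numbered 1 to 3 in each group, but the labels do not say whether they came from separate cultures, so p-values measure only the spread between these samples, which may be technical.

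Uhrf2 fell in all 3 siUhrf2 libraries. The gene lies on the plus strand of chromosome 19 from 30030513 to 30093722 (GRCm38, GENCODE M21, protein-coding). Its level was 8992 ± 82.6 normalized counts in siCtrl (SD, n = 3) and 2841 ± 88.2 in siUhrf2 (SD, n = 3), or 107 against 33.7 FPKM, so that 31.6% of the control level remained. The siCtrl libraries held 8899, 9058 and 9018 normalized counts and the siUhrf2 libraries 2942, 2805 and 2777. The log2 fold change was -1.66 (SE 0.034), with the lowest adjusted p of all genes tested (limma adjusted p = 7.58e-11). The exact two-sided permutation test gave p = 0.10, the smallest value that 3 against 3 libraries allow. Uhrf1, on chromosome 17 from 56303321 to 56323486, had 8314 ± 609 normalized counts in siCtrl and 8480 ± 500 in siUhrf2 (SD, n = 3), a log2 difference of 0.03 (SE 0.059, limma adjusted p = 0.69), smaller than the spread between replicates.

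**Figure D1:**
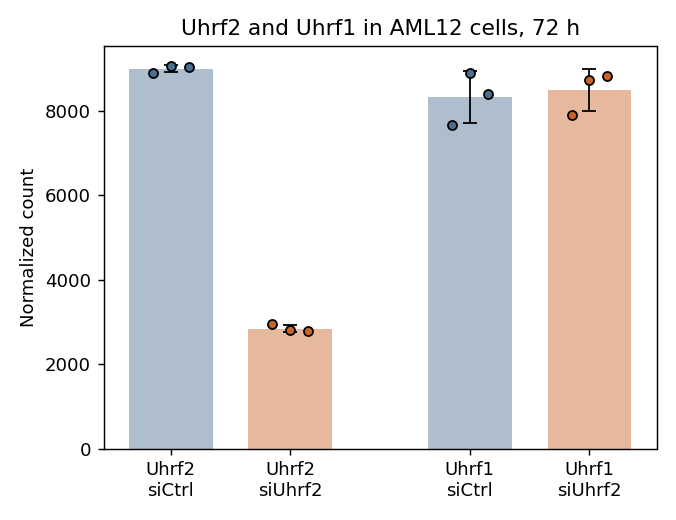
Normalized counts of Uhrf2 and Uhrf1 per library; bars are means of 3 libraries, error bars the SD and points the libraries. Uhrf2 lies between 8899 and 9058 in siCtrl and between 2777 and 2942 in siUhrf2, while the Uhrf1 ranges overlap.

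Many transcripts differed between the groups, most by small amounts. Of 11343 genes with a mean of at least 1 FPKM, 6919 (61.0%) changed at a limma adjusted p under 0.05, 3396 of them higher and 3523 lower in siUhrf2. The median fold of the changed genes was 1.22, and 45.5% of them changed by under 1.2-fold. A change of at least 2-fold was estimated for 126 higher and 175 lower genes. In 7561 genes (66.7%) the ranges of the groups did not overlap, where chance gives 10%. Tested against a change of 1.5-fold with limma treat, 342 genes passed, 137 higher and 205 lower. The first principal component held 78.6% of the variance and separated the groups.

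Among the genes with the largest rises, Ms4a4b went from 155 ± 9.29 to 766 ± 82.1 normalized counts (4.92-fold, limma adjusted p = 8.30e-09) and Lgals2, a galectin, from 392 ± 23.5 to 1879 ± 164 (4.78-fold, limma adjusted p = 1.24e-09). Ms4a4b lies on chromosome 19 from 11443553 to 11467055 and Lgals2 on chromosome 15 from 78850860 to 78855529. Lgals2 overlaps Cdc42ep1 on the opposite strand, and whether the authors used strand is not given in the sources used here, so its level is uncertain. The heparin-binding protein gene Fgfbp1 rose 3.15-fold, the interferon-inducible gene Ifi202b 3.05-fold and the chemokine gene Ccl9 3.04-fold. The epithelial genes Upk1b, Emp1 and Scel rose 2.92-fold, 2.83-fold and 2.71-fold, and the transcription factor gene Klf4 rose 2.66-fold. Insig1, Scd1 and Pmvk, genes of sterol and lipid synthesis, completed the 12 and are described with their groups.

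The falls reached further than the rises. Cyp4a12a, a fatty acid hydroxylase gene, went from 1743 ± 356 to 77.0 ± 39.6 normalized counts (a log2 change of -4.58, SE 0.41, limma adjusted p = 0.000595). Hp, which encodes the acute phase protein haptoglobin, went from 5087 ± 559 to 274 ± 75.1 (log2 change -4.24, SE 0.24, limma adjusted p = 0.00010). They lie on chromosome 4 from 115299046 to 115332815 and on chromosome 8 from 109575128 to 109579172. Cd74, the invariant chain of MHC class II, fell with a log2 change of -4.03, and the matricellular gene Postn with -4.24. Arap3 changed by -3.00, Saa3, a serum amyloid gene, by -2.89, the cytokine gene Il11 by -2.84 and Tmem238l by -2.62. Ly6a, the NADPH oxidase gene Cybb, Gstm2 and the complement gene C1s1 changed by -2.24, -2.19, -2.08 and -1.93. All 24 of these genes passed the limma test and had groups without overlap, and Il11 did not pass the test against 1.5-fold. Cyp4a12a, Gstm2, Ly6a, Ms4a4b, Ifi202b, Saa3 and C1s1 have close paralogs with which pseudo-aligned reads can be shared, so the split between copies is uncertain.

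**Figure D2:**
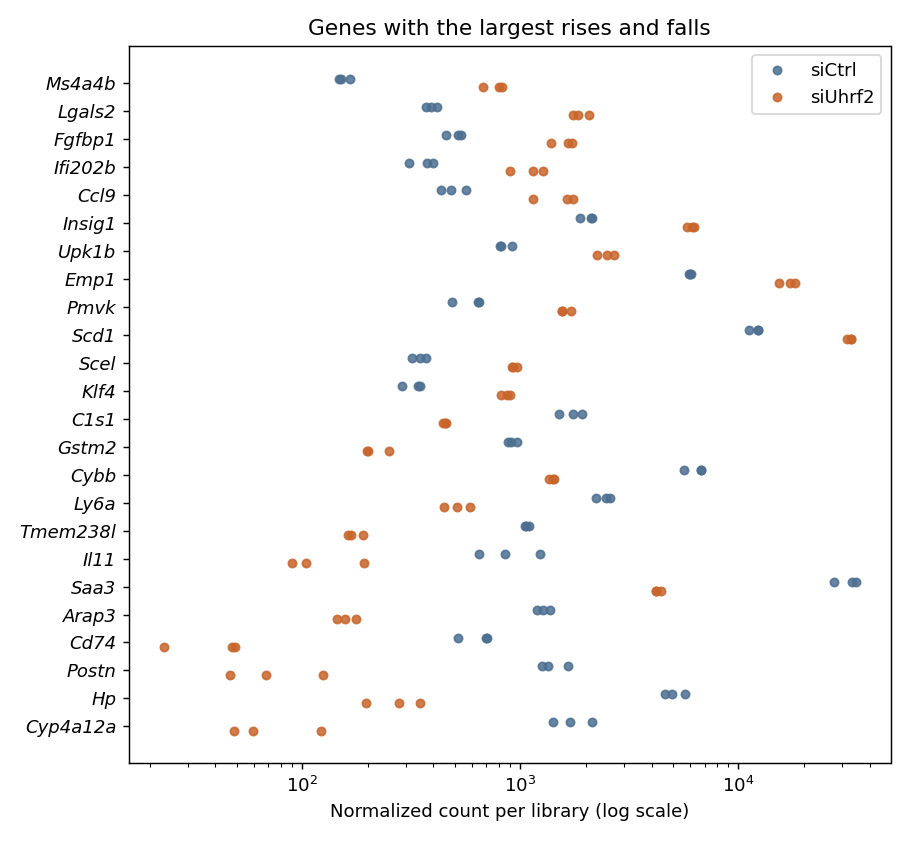
Normalized counts per library, on a log axis, of the 12 genes with the largest rises and the 12 with the largest falls; each point is 1 of 3 libraries per group. The groups do not overlap in any of the 24 genes.

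Genes of cholesterol synthesis rose together. All 24 measured members (members of a list count as measured at a mean of at least 1 FPKM) rose (24 adjusted over the list alone), with a median log2 fold change of 1.01 (camera adjusted p = 2.52e-15; adjusted p = 0.46 with an estimated correlation). Insig1, the sterol-responsive retention factor of SCAP, went from 2046 ± 139 to 6072 ± 205 normalized counts (2.97-fold). Pmvk rose 2.74-fold, Nsdhl 2.26-fold, Fdft1, which encodes squalene synthase, 2.16-fold and Idi1 2.05-fold. In fatty acid synthesis and lipid storage, 13 of 19 genes rose, 5 fell and 1 did not pass, with the same counts adjusted over the list alone (median 0.33, camera adjusted p = 0.0010; adjusted p = 0.46 with an estimated correlation). Scd1, the stearoyl-CoA desaturase, rose 2.72-fold to 32349.8 ± 681 normalized counts, Elovl6 2.01-fold, Fads1 1.71-fold and Acaca, the acetyl-CoA carboxylase, 1.53-fold. For fatty acid oxidation and PPARa targets 7 of 21 genes rose, 6 fell and 8 did not pass, with the same counts adjusted over the list alone (camera adjusted p = 0.91). Its median was -0.01 and its mean 0.01, camera pointed up and fry down, and the sign of the median turned under other scalings. Cpt1a fell by 0.45 on the log2 scale, while Acadl and Acaa1b rose by 0.36 and 0.64.

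Most measured genes of the inflammatory and interferon lists fell. Of 26 measured genes of NF-kB, cytokines and the acute phase, 18 fell, 3 rose and 5 did not pass, also adjusted over the list alone (median -0.43, camera adjusted p = 8.92e-05; adjusted p = 0.46 with an estimated correlation). The adhesion molecule gene Icam1 went from 6017 ± 444 to 2375 ± 74.8 normalized counts, and Cxcl2, Ccl20 and the NF-kB subunit gene Rela changed by -1.17, -0.80 and -0.55 on the log2 scale. The 3 that rose were Il1rn, which encodes the interleukin 1 receptor antagonist, Cxcl5 and Cxcl1. In the interferon response 9 of 12 genes fell, 0 rose and 3 did not pass, with the same counts adjusted over the list alone (median -0.42, camera adjusted p = 0.0021; adjusted p = 0.46 with an estimated correlation). Irf9, Ifi35 and Ddx58 changed by -0.59, -0.47 and -0.42. Among the markers of macrophages and leukocytes Csf1r and Cd68 fell, at 2.62 and 3.02 FPKM on average, while Cd14 had 6097 ± 237 against 6137 ± 347 normalized counts (limma adjusted p = 0.88). That list of 3 measured genes was not called (camera adjusted p = 0.17), and its counts were the same adjusted over the list alone.

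Of 23 measured genes of the extracellular matrix, TGF-beta and epithelial-mesenchymal list, 14 fell, 4 rose and 5 did not pass, also adjusted over the list alone (median -0.34, camera adjusted p = 0.010; adjusted p = 0.38 with an estimated correlation). The basement membrane collagen gene Col4a2 went from 17540.1 ± 523 to 9098 ± 345 normalized counts, and Ccn1, Sparc and Itga5 changed by -0.85, -0.61 and -0.60 on the log2 scale. The risers were Cdh1, which encodes E-cadherin, the intermediate filament gene Vim, Smad7 and Tgfb1. Postn was the 1 measured marker of fibroblasts and stellate cells and fell (camera adjusted p = 0.13). Of 6 cholangiocyte and progenitor markers 3 rose, 2 fell and 1 did not pass (camera adjusted p = 0.35), with Krt19 at 1.98-fold, Cd24a at 1.34-fold, and Krt7 lower by a log2 change of -0.16. Egfl7, the 1 measured endothelial marker, had a log2 difference of -0.07 and did not pass (camera adjusted p = 0.96). The counts of these marker lists were the same adjusted over the list alone.

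Mitotic genes rose by small amounts. In the G2/M and mitosis list 26 of 36 genes rose, 1 fell and 9 did not pass (28 rose and 1 fell adjusted over the list alone), with a median of 0.16 (camera adjusted p = 7.12e-05; adjusted p = 0.49 with an estimated correlation). Ncapg, Kif11, Bub1b and Ect2 rose 1.31-fold, 1.28-fold, 1.28-fold and 1.27-fold, and Foxm1, a transcription factor gene of mitotic genes, was the one that fell. The G1/S and DNA replication list was divided, with 10 of 36 higher, 11 lower and 15 not passing, also adjusted over the list alone (camera adjusted p = 0.60). Lig1 rose 1.48-fold, Gins1 1.40-fold and Mcm3 1.22-fold, while Ccne2 changed by -0.53. Among p53 targets 17 of 24 fell, 5 rose and 2 did not pass, also adjusted over the list alone (median -0.16, camera adjusted p = 0.0499; adjusted p = 0.49 with an estimated correlation). Btg2 and Trp53inp1 changed by -0.89 and -0.85, and Ei24 and Tigar rose by 0.49 and 0.46. The p53 call was lost without siCtrl replicate 1 (adjusted p = 0.060), siUhrf2 replicate 2 (0.063) or siUhrf2 replicate 3 (0.061), and under 3 of the other 4 scalings (0.053, 0.059 and 0.066). For apoptosis regulators 10 of 22 fell, 4 rose and 8 did not pass (11 fell and 4 rose adjusted over the list alone; camera adjusted p = 0.20), with Birc2, Mcl1 and Apaf1 at -0.45, -0.40 and -0.36.

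Most listed genes of ribosomal proteins and of oxidative phosphorylation rose slightly. Of 30 ribosomal protein genes 28 rose and 2 did not pass, also adjusted over the list alone (median 0.20, camera adjusted p = 3.08e-06; adjusted p = 0.49 with an estimated correlation; median 0.12 under quantile normalization), among them Rpl11 and Rps2 at 1.34-fold, Rplp1 at 1.24-fold and Rpl8 at 1.19-fold. Of 29 genes of oxidative phosphorylation 20 rose, 2 fell and 7 did not pass (21 rose and 2 fell adjusted over the list alone), with a median of 0.14 (camera adjusted p = 8.92e-05; adjusted p = 0.38 with an estimated correlation). Sdhb and Atp5o rose 1.40-fold and 1.24-fold.

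The DNA methylation machinery moved in both directions. Of 20 genes in the UHRF family and DNA methylation list 4 rose, 5 fell and 11 did not pass, also adjusted over the list alone (median -0.02, camera adjusted p = 0.82). Tdg, the thymine DNA glycosylase gene, rose 1.39-fold and Ehmt1 1.16-fold, while Tet3, which encodes a 5-methylcytosine dioxygenase, changed by -0.47. The maintenance methyltransferase gene Dnmt1 had a log2 difference of 0.07 and did not pass. Of the germline and imprinted genes with methylated promoters 5 of 30 reached a mean of 1 FPKM and were tested, of which 2 fell, 0 rose and 3 did not pass, also adjusted over the list alone (camera adjusted p = 0.27). Impact and Peg3, both imprinted, were the ones that fell, by log2 changes of -0.89 and -0.34, and Sgce had a difference of 0.09. The siRNA machinery, which processes or carries the transfected RNA, held 7 falls and 1 rise among 12 genes, with 4 not passing (8 falls and 1 rise adjusted over the list alone; median -0.14, camera adjusted p = 0.0499; adjusted p = 0.46 with an estimated correlation). Tarbp2, Tnrc6a and Tnrc6c changed by -0.32, -0.26 and -0.18, and Prkra rose 1.15-fold. That call was lost without any 1 of siCtrl replicates 1, 2 and 3 (adjusted p = 0.055, 0.054 and 0.050) or siUhrf2 replicates 2 and 3 (0.070 and 0.061), under every other scaling (0.050 to 0.059) and at a mean of at least 5 FPKM (0.10).

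The other hepatocyte and stress lists were not called. Among hepatocyte secreted proteins and transcription factors 7 of 17 genes fell, 1 rose and 9 did not pass, also adjusted over the list alone (median -0.19, camera adjusted p = 0.097). Ambp went from 3057 ± 76.3 to 1054 ± 166 normalized counts, Rbp4, the retinol carrier, changed by -0.81, Foxa3 by -0.38 and Trf, which encodes transferrin, by -0.32, and the riser was Hnf4a. Of 10 genes of cytochrome P450, conjugation and bile acid transport 2 rose, 3 fell and 5 did not pass, also adjusted over the list alone (camera adjusted p = 0.98). Its median of 0.02 and mean of 0.07 were positive while camera pointed down, and Gsta3 rose 1.61-fold where Gstm1 changed by -0.92 and Cyp2d22 by -0.78. In gluconeogenesis, glycolysis and the urea cycle 13 of 22 entries rose, 6 fell and 3 did not pass, also adjusted over the list alone (median 0.23, camera adjusted p = 0.093). Eno1, Pkm and Gapdh rose 1.38-fold, 1.36-fold and 1.36-fold, and Pklr, the liver pyruvate kinase gene, changed by -0.46. For NRF2 and oxidative stress 14 of 23 rose, 6 fell and 3 did not pass, also adjusted over the list alone (camera adjusted p = 0.13), with Taldo1 at 2.33-fold, Tkt at 1.40-fold, Osgin1 at -1.14 and Cat, the catalase gene, at -0.68. Of 30 unfolded protein response genes 6 rose, 11 fell and 13 did not pass, also adjusted over the list alone (camera adjusted p = 0.60). Its median was -0.03 and camera pointed down while its mean was 0.05, Dnajb9, Syvn1 and Atf6 changed by -0.65, -0.37 and -0.32, and Chac1, a glutathione-degrading enzyme gene of the ATF4 response, rose 2.27-fold.

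**Figure D3:**
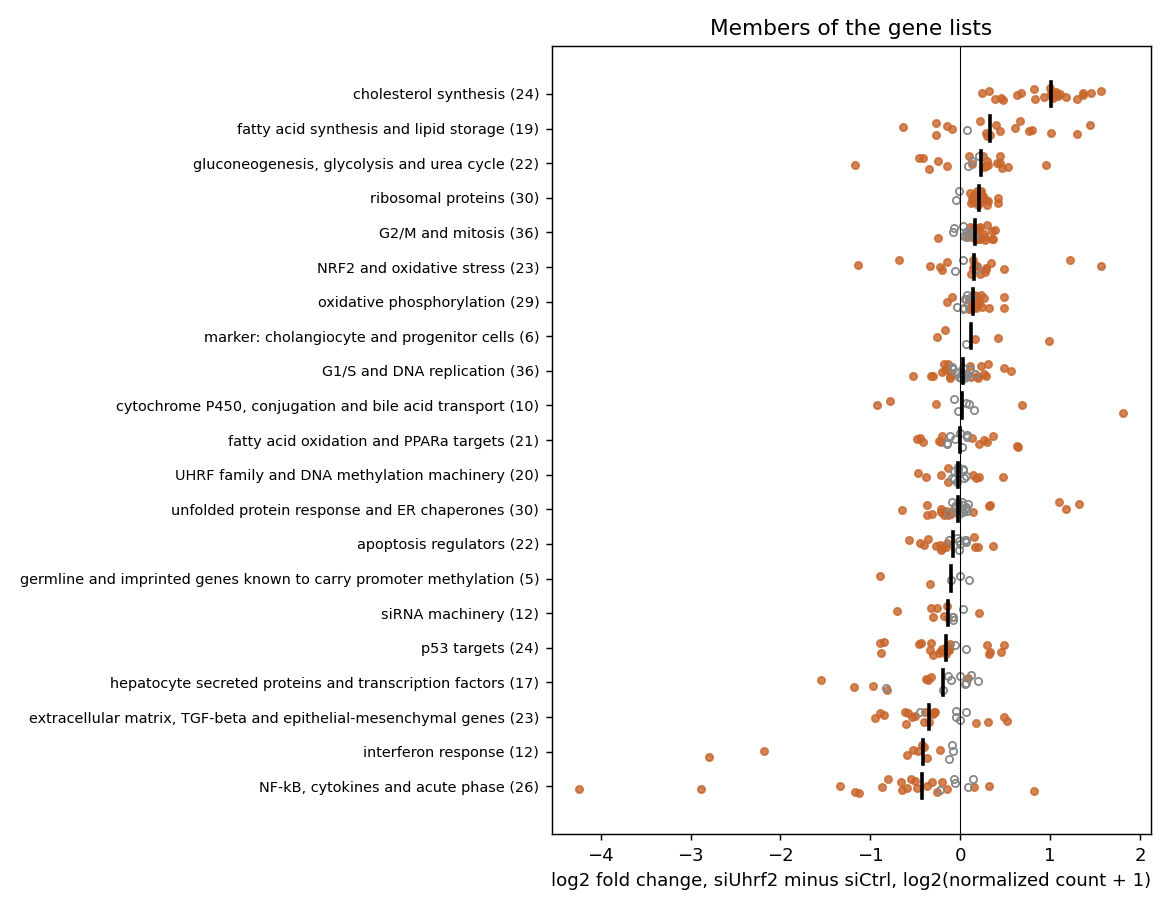
Log2 fold change (siUhrf2 minus siCtrl) of each measured member of the 21 lists with at least 5 measured genes; filled points passed the limma test, open points did not, black bars are list medians and numbers in brackets are measured genes. Cholesterol synthesis lies highest with a median of 1.01, and NF-kB, cytokines and acute phase lowest with -0.43; the sign of the median of fatty acid oxidation turned under other scalings.

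In all, camera called 10 of 24 lists, 5 up and 5 down, and 0 with an estimated correlation, where the smallest adjusted p was 0.38. At the preset correlation camera also called 4 to 10 lists in each of the 9 splits that mixed the groups, in which 0 genes were called. Part of the siUhrf2 difference remains in such splits, so their list calls need not be false. The fry test, which asks whether a list's genes move on balance in one direction without comparing them with other genes, called 16.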

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

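The fits on log2(FPKM + 1) and without genes carrying the control-duplex heptamers described under the other observations were chosen after the data were seen. The number of changed genes, 6919, lay between 5354 (adjusted p under 0.01) and 7435 (no filter on low values) except with limma treat against 1.5-fold, which by construction asks for more and called 342. Leaving out 1 library gave 6010 to 7047 genes, and 0 genes were called in opposite directions under any alternative but the fit without carriers, where this was not counted. The share of higher genes stayed between 46.3% and 53.1% under other scalings. Uhrf2 kept its call under 17 alternatives, with log2 fold changes between -1.69 and -1.64, and between -1.69 and -1.65 when 1 library was left out. Camera called 0 lists with an estimated correlation in place of 10, for which the cause was not tested. The extracellular matrix and siRNA machinery lists had estimated correlations of -0.036 and -0.049, below the preset 0.01, and still lost their calls. A higher correlation is therefore not what cost these lists their calls. The fry test, which asks another question, called 16 lists. Other scalings and the filter at 5 FPKM gave 8 to 9 lists and leaving out 1 library 8 to 10. The sign of Uhrf1 turned without siCtrl replicate 1, with a range of -0.0277 to 0.0793 when 1 library was left out. That of Cd14 turned with equal library totals (-0.00473), on log2(FPKM + 1) (-0.00467), without siCtrl replicate 2 (-0.0202) and without siUhrf2 replicate 1 (-0.0375), with 0.0358 the highest value when 1 library was left out. Neither gene was called, and the cause was not tested. Without carriers of the heptamers the glycolysis list was gained (adjusted p = 0.033) and the siRNA machinery list lost (0.074). Not run were the DESeq2 Wald test and the edgeR-based fits, which need counts and were not tried on rounded estimated reads, with limma treat in place of glmTreat.

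The labels do not say that the replicate numbers pair the libraries, so the main fit was unpaired. Deviations from the group means correlated by 0.18, 0.24 and 0.066 between same-numbered libraries across genes. All 6 libraries correlated best with their own number, a hint from the data and not the design. With the number as a block 7248 genes and 10 lists were called, and Uhrf2 stayed at -1.66.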

Other observations

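The splits of the samples were planned before the data were examined, with their bound written afterwards, and the other tests of this part were chosen after the results were seen. Families of at least 6 tested genes whose symbols share a stem were tested with camera as 295 sets, of which 9 changed and 0 did with an estimated correlation (adjusted p = 0.89 for each named here). All 11 genes of the Eef stem, translation elongation factors and the enzymes that modify them, rose (median 0.25, camera adjusted p = 0.033), with Eef2k, the kinase of elongation factor 2, at 1.05. All 7 Cct chaperonin subunits (median 0.24, camera adjusted p = 0.038) and all 6 Smc genes, which encode structural maintenance of chromosomes proteins (median 0.26, camera adjusted p = 0.038) rose too. Of 49 Mrpl genes of the mitochondrial ribosome 24 rose, 3 fell and 22 did not pass (camera adjusted p = 0.012), and of 29 Mrps genes 12 rose, 0 fell and 17 did not pass (camera adjusted p = 0.036). Of 11 Atxn-stem genes 8 fell (median -0.27, camera adjusted p = 0.036). In contrast to the nuclear respiratory chain genes, 6 of 7 mitochondrially encoded mt-Nd genes fell (median -0.29), but as a set they did not pass (camera adjusted p = 0.12). These medians kept their signs under all 4 other scalings, where the lowest Cct median was 0.15.

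All 5 tested genes of the interferon-inducible PYHIN family on chromosome 1 between 173747293 and 173982744 rose, with log2 fold changes from 0.72 to 1.61 (Ifi203, Ifi202b, Mndal, Ifi204 and Ifi211), and their summed normalized counts went from 1183 ± 182 to 2822 ± 421 (SD, n = 3). The 8 tested genes of the Ifi stem went both ways, with 4 rises and 4 falls (camera adjusted p = 0.99). Those 4 rises were Ifi202b, Ifi203, Ifi204 and Ifi211 of this cluster. The GTPase genes Gbp4, Gbp6 and Gbp10 fell, by log2 changes of -2.02, -1.08 and -1.04, as did Irgm1 at -0.41. The surface protein genes Ly6a, Ly6c1 and Ly6f on chromosome 15 changed by -2.24, -1.88 and -1.85. Of 6 tested genes of the Ly stem, which holds these 3, 5 fell and 1 did not pass (median -1.08, camera adjusted p = 0.036; adjusted p = 0.89 with an estimated correlation). The genes named here were picked after their values were seen, the PYHIN and GTPase genes were not tested as sets of their own, and paralogs within each cluster can share reads.

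Genes with TCGGAGA in the 3′ UTR were higher in siUhrf2: in a scan of 16344 heptamers over 10733 genes, adjusted for UTR length and GC content, CGGAGAA (z = 8.57, 351 genes), TCGGAGA (z = 8.40, 282 genes) and ACGGAGA (z = 6.60, 372 genes), which shares only the 6-base core with TCGGAGA, ranked first, above the highest score of 5.64 in any of 1000 shuffled gene orders. Base composition is argued against as the whole cause, since TCGGAGA stood 7.94 SD above the 419 heptamers of the same letters, where the heptamer furthest above those of its own letters stayed under 4.87 SD in 95% of shuffles and reached 7.73 SD in any. Open is repression in the siCtrl libraries through the seed of a control siRNA: the mean log2 fold change of genes with TCGGAGAA lay 0.187 above that of genes with the core CGGAGA alone, but these classes come from the scan itself, so the difference does not decide it. TCGGAGA and TGTCACG (z = 4.83, above the 4.30 reached by 5% of shuffles) are complementary to positions 2 to 8 of the strands of a widely used non-silencing duplex (UUCUCCGAACGUGUCACGU), which may have been the control here although the labels do not say so and the match was noticed after the scan. A change after Uhrf2 loss was not tested against it. Carriers held an excess of 108 among 3251 risers with a UTR (3.31%). Without them, 6323 of 10461 tested genes and 10 lists were called, with the glycolysis list gained and the siRNA machinery list lost. Indirect effects of a control siRNA would remain among the other genes, so these counts do not give its whole share. At the low end of the scan GCACTTT ranked lowest (z = -4.22), and 114 of 1000 shuffles held a heptamer as low. The samples hold no other siRNA group against Uhrf2 and no rescue. Effects of the siUhrf2 RNA on other transcripts therefore cannot be told apart from Uhrf2 loss.

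Clustered zinc finger genes rose together on chromosome 2. Of 29 tested members between 175010241 and 178078476, 23 rose, 0 fell and 6 did not pass (median 0.60), while 287 Zfp-named genes elsewhere had a median of -0.03. Reads moved among these 29 members are argued against as the whole cause, since such moves leave their sum alone. The sum rose by 0.586 on the log2 scale (SE 0.029), from 13768 ± 430 to 20667 ± 293 normalized counts (SD, n = 3). Moves to or from similar copies that are not among the 29 would change the sum and are not covered. Sites of the control duplex are argued against as well, for the 23 members with an annotated 3′ UTR. These carried none, 17 of them rose, and their median was 0.546 (SE 0.18). That SE treats the members as independent, although they can share reads. A change of 1 or a few copies whose reads spread to the rest stays open, and so does an effect of Uhrf2 loss, which was not tested apart from it.

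The small rise of ribosomal protein and oxidative phosphorylation genes was set against technical trends. Fold changes correlated weakly with GC content (Spearman rho -0.14 across 11335 genes, which are not independent) and length (-0.08). With trends in GC content, length and level removed, the median went from 0.20 to 0.14 (SE 0.021) for ribosomal proteins. For oxidative phosphorylation it went from 0.14 to 0.094 (SE 0.036). Both stayed positive, while part of the rise goes with the trend. These SEs treat genes as independent, although the estimated inter-gene correlation was 0.80 for ribosomal proteins and 0.035 for oxidative phosphorylation. They are therefore too small, and the test does not decide whether the trend is the whole cause. Under the 4 other scalings the lowest median of both lists was 0.120, for ribosomal proteins under quantile normalization, with 0.22, 0.22 and 0.19 under the other scalings. Those others use 1 factor per library, and the median of all tested genes lay only between -0.019 and 0.012 under them. They could thus hardly have removed the rise. Quantile normalization left oxidative phosphorylation at 0.137, which argues against scaling of that kind as the whole cause, while part of the ribosomal rise goes with it. RNA quality was not tested, and an effect of Uhrf2 loss remains a possible explanation.

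For 3 against 3 libraries there are 10 splits, too few for a share under 0.05. The real split gave 6919 genes and the highest of the other splits 0, so 1 split gave as many. For lists the real split gave 10 and the 9 others, with 0 genes each, gave 4 to 10, and 3 splits, the real one included, gave as many. The 9 others set unequal numbers of siUhrf2 libraries against each other, so part of the difference remained and their list calls need not be false. The rest of the difference widened the spread within their groups, which holds down gene calls. These splits therefore do not show what a grouping without any difference would give.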
